A study of Homo sapiens with 29 samples.

How the data were processed

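HCT116 cells, a human colorectal carcinoma line, received siRNA against DAXX or non-targeting siRNA, each with or without 10 mM crotonate, per the labels. DAXX encodes a chaperone of the histone variant H3.3. The labels give 35 nM siRNA for DAXX and 25 nM for the non-targeting control, so the 2 siRNA arms differ in dose as well as in target. The series text gives 18 h of crotonate and the sample protocol gives 48 h. The 16 RNA libraries form 4 groups of 4. The 12 ChIP libraries, made with a pan antibody against crotonyllysine (Kcr), form groups of 4 with each siRNA without crotonate and 2 with each siRNA and crotonate. There is 1 input library, which the labels assign to cells with DAXX siRNA.

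Per the submitters' processing notes, RNA reads were trimmed with Trim Galore 0.6.2 and ChIP reads with Trim Galore 0.6.5, both with cutadapt 2.3. The same notes name HISAT2 2.2.1 for RNA alignment, Bowtie2 for ChIP alignment and MACS for regions, all on GRCh38. How regions of single libraries were combined, and which strand was counted, are not given in the sources used here.

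Both deposited tables hold log2 values. In the RNA table they are log2 RPM (reads per 10 to the power of 6 reads) without division by gene length, and 0 reads were entered as 0.9 read before scaling. In the ChIP table they are log2 reads in 49916 regions after multiplication by 1 factor per library, and the input is a column of its own that was not subtracted. Undoing the factor of each library gave whole reads for 100% of the values. The tolerance was 0.01 read and widened in proportion to the count, so it tells little at the highest counts.

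The main test was limma 3.58.1 in R 4.3.3, fitted to the deposited log2 values with 1 coefficient per group, a trended prior variance and Benjamini-Hochberg adjustment within each comparison; calls mean an adjusted p under 0.05. The plan, written before the data were examined, put a count model first and limma next. The tables hold log2 values, so limma became the main test. Reads recovered from them were used in limma-voom as an added alternative, chosen after the data were seen. RNA genes needed at least 0.25 RPM in at least 4 libraries: 17973 of 38148 genes were tested, and 10458 had no read in any library. All 49916 regions were tested. The interaction is the DAXX siRNA effect with crotonate minus that without. Fold changes are log2 unless a plain ratio is given, errors are SD of libraries in a group, and SE is the moderated standard error from limma.

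Libraries numbered 1A and 1B in the ChIP table differed from each other by no more than read sampling in the non-targeting pair (chi-squared over degrees of freedom 1.009, p = 0.0808) and barely more in the DAXX siRNA pair (1.013, p = 0.0297). Other pairs of the same group gave 1.036 to 1.426. Group means and SD for ChIP therefore count 1A and 1B as 1 sample (n = 3 without crotonate, n = 2 with). The planned limma fit keeps them apart, as do the comparisons of anti-Kcr signal with RNA level. Counts with them merged stand beside the calls of that fit.

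Genes are named by a rule set before the tests. It takes DAXX, then up to 8 called genes of largest change each way in each RNA comparison (5 for the interaction). These must have an official symbol, a mean in the higher group at or above the median of expressed genes (log2 RPM 4.09) and, outside the interaction, every library of 1 group above every library of the other. It adds the 2 called genes with the smallest adjusted p each way from each treatment list with at least 3 called genes. For ChIP it takes up to 5 called regions each way by size, or the 3 with the smallest p each way where none was called. Some genes that the rule takes, and 1 gene list, are not reported here. Other genes named below were chosen after their values were seen. Of 34 gene lists, 29 cover the treatment, 2 cover RNA quality and 3 cover other cell types. Each list was tested with camera in limma at a fixed correlation of 0.01 between genes and again with the correlation estimated from the data. Counts "over the list alone" adjust p within the list only.

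P-values measure the spread between libraries only, since the labels do not state whether the replicates are separate cultures. Gene coordinates and strands are those of the deposited tables, and a region is placed at a gene start when it lies within 2 kb of one. Exons and introns were not analysed here. Reads were simulated with changes up or down only in genes and regions at or above the median mean level. Rates for weaker ones were not measured. Among the changed genes, 1.5-fold changes were called for 97, 97, 95.5 and 97% in the 4 RNA comparisons and for 58.2% in the interaction. The 2-fold changes were called for 100% in each. False calls among genes were 10 of 208, 15 of 213, 12 of 209 and 8 of 206, and 12 of 184 in the interaction. These lay above the 5% aimed at for crotonate with non-targeting siRNA, DAXX siRNA with crotonate and the interaction. For regions, 2-fold changes were called for 97, 89.6, 65.7 and 77.6%, and for 47.8% in the interaction, and 1.5-fold changes for only 47.8, 47.8, 16.4 and 26.9%, and 7.46% in the interaction. False calls among regions were 7 of 170, 23 of 180, 15 of 135 and 17 of 153, and 7 of 110 in the interaction, so above the 5% aimed at in 4 of these 5. The simulation drew 1A and 1B as independent libraries, which the deposited ones are not. The shares of changed regions called may therefore be too high.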

Results

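DAXX transcript remained at 23.9% of the non-targeting level after DAXX siRNA without crotonate and at 19.3% with it. DAXX (ENSG00000204209, chromosome 6, 33318558 to 33323016, minus strand) fell from 103 ± 1.6 to 24.6 ± 2.06 RPM without crotonate (log2 fold change -2.07, SE 0.125, n = 4 per group, limma adjusted p = 1.23e-08). With crotonate it fell from 100 ± 3.38 to 19.3 ± 4.67 RPM (-2.41, adjusted p = 7.4e-10). Crotonate alone left DAXX in place with non-targeting siRNA (-0.038, adjusted p = 0.884). It lowered the residual transcript in DAXX siRNA cells by 0.38 log2 units (adjusted p = 0.0452), a call that was lost in 9 of 16 other settings. The level of DAXX in every library is drawn in the chart of DAXX transcript.

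**Figure D1:**
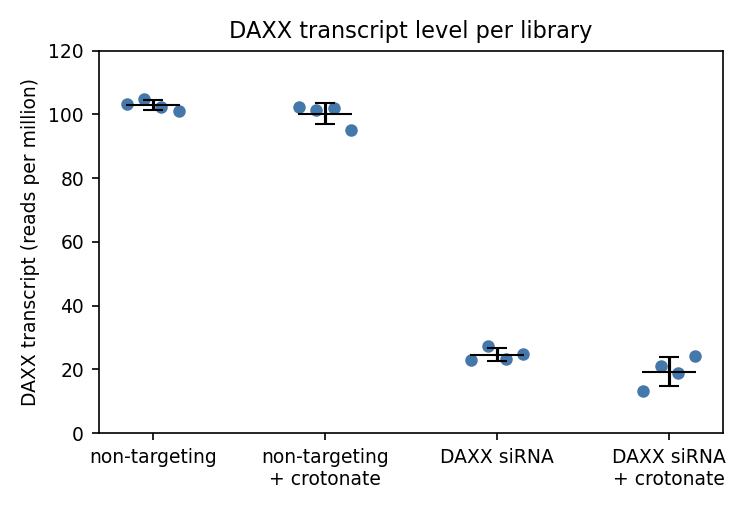
DAXX transcript in RPM in each RNA library, by siRNA and crotonate. Bars are group means, n = 4 libraries per group.

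Without crotonate, DAXX siRNA raised HMGA2, an AT-hook protein of chromatin, from 171 ± 27.5 to 298 ± 17.8 RPM (log2 fold change 0.82, SE 0.105, n = 4, adjusted p = 0.000463). GAS6, the ligand of the TAM receptor kinases, rose from 77.9 ± 13 to 128 ± 13.6 RPM. The secreted carboxypeptidase gene CPA4 (0.57, lost in 7 of 16 other settings), the lectin gene LGALS3 (0.49) and the ribosome maturation gene SBDS (0.49) also rose. AP3S1, a subunit of the AP-3 adaptor (0.51), and the zinc finger homeobox gene ZHX1 (0.51) were called in the main fit but lost in 9 and 13 of 16 other settings. FTH1, the ferritin heavy chain gene, was picked after its value was seen and rose from 1808 to 2498 RPM (0.47, adjusted p = 0.0024).

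Several genes besides DAXX fell. PARM1, a mucin-like membrane protein gene, fell from 19 ± 1.46 to 8.22 ± 0.605 RPM (log2 fold change -1.21, SE 0.0934, n = 4, adjusted p = 4.56e-07). IGSF3, an immunoglobulin superfamily member, fell from 62.1 ± 4.03 to 29.3 ± 3.26 RPM, and the kinase gene MAP3K3 from 34.6 ± 2.39 to 16.5 ± 1.85 RPM. ATAD2, a bromodomain ATPase that binds acetylated histones, fell from 291 ± 42.3 to 170 ± 15.3 RPM (-0.76). The torsin gene TOR1B (-0.83), the ferric reductase gene CYBRD1 (-0.75) and the kinase gene PIM1 (-0.73) followed. UHRF1, which couples DNA replication to maintenance methylation, was picked after its value was seen and fell from 260 to 177 RPM (-0.55, adjusted p = 0.00426). SPARC, a matricellular gene picked the same way, fell from 8.23 to 4.35 RPM (-0.92).

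These genes belong to a small set: 18 genes were higher and 55 lower with DAXX siRNA without crotonate, out of 17973 tested with limma. Unadjusted p fell under 0.05 for 2189 genes (12.2%), and limma-voom called 16 and 47. With only these 2 groups in the model, 7 and 22 remained. In the fit of all groups 5 called genes, all lower, changed by at least 1 log2 unit: DAXX, PARM1, IGSF3, MAP3K3 and SMIM40, which overlaps DAXX (-2.15) and falls outside the naming rule. Higher calls fell to 11, 10 and 10 without DAXX siRNA libraries 1, 2 or 3. Lower calls fell to 35 and 29 without DAXX siRNA libraries 1 or 3, and to 34 and 35 without non-targeting libraries 1 or 4.

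As groups, targets of NRF2 shifted upwards without crotonate, with FTH1 the 1 of 24 called higher and none lower (6 and 0 over the list alone; camera adjusted p = 0.0026, 0.291 with the correlation estimated from the data). Genes of G2 and mitosis shifted upwards with 0 of 36 called (adjusted p = 0.0026, estimated 0.824). Ribosomal protein genes did so with 0 of 81 called (adjusted p = 0.0406, estimated 0.824). Genes of H3.3 chaperones and DAXX partners gave 0 higher and 1 lower of 29, DAXX itself (1 and 1 over the list alone; adjusted p = 0.811, estimated 0.923), and genes of crotonylation writers, erasers and readers 0 of 27 (2 and 1; adjusted p = 0.639, estimated 0.824).

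With crotonate present, many of the same genes responded to DAXX siRNA. HMGA2 rose from 173 ± 10.6 to 319 ± 38.5 RPM (log2 fold change 0.88, n = 4, adjusted p = 7.73e-05), GAS6 from 80.5 ± 4.27 to 148 ± 22.5 RPM, and CPA4 from 25 ± 3.12 to 49.6 ± 7.09 RPM. MDGA1, a GPI-anchored adhesion gene, rose from 11.1 ± 1.73 to 24 ± 2.06 RPM (1.12, adjusted p = 0.000291) and was not called without crotonate (adjusted p = 0.0524). SEMA7A, a GPI-anchored semaphorin (0.75), and the mucin-type glycosyltransferase gene GALNT5 (0.71) also rose. GAS6-AS1 (0.65) overlaps GAS6 on the opposite strand, so its reads cannot be told apart from those of GAS6 where the counting strand is unknown.

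PARM1 fell again, from 41.3 ± 0.522 to 16.2 ± 1.96 RPM (log2 fold change -1.36, n = 4, adjusted p = 3.03e-08), as did MAP3K3 (-1.28) and IGSF3, from 110 ± 3.25 to 45.6 ± 4.12 RPM. ATAD2 fell from 282 ± 14.1 to 123 ± 7.85 RPM (-1.20), as did CYBRD1 (-1.065) and PIM1 (-0.92). SMIM40, a small membrane protein gene, fell from 17.4 ± 1.27 to 3.29 ± 1.17 RPM (-2.48), but it overlaps DAXX and may count DAXX reads. Of replication genes, UHRF1 fell from 219 ± 15.4 to 142 ± 17.5 RPM (-0.63, adjusted p = 6e-04), the clamp loader gene RFC4 fell (-0.43) and the cyclin gene CCNE1 rose (0.37), the last a call lost in 8 of 16 other settings. Picked after their values were seen, SPARC fell by 1.67 log2 units (adjusted p = 1.6e-07) and the heme oxygenase gene HMOX1 rose by 0.52.

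In all, 70 genes were higher and 120 lower with DAXX siRNA in the presence of crotonate (limma-voom 90 and 147). Of these, 2 and 14 changed by at least 1 log2 unit, the 2 higher ones being MDGA1 and, picked after its value was seen, SPNS3 (1.22, adjusted p = 0.0382). Higher calls ranged from 25 to 37 when 1 of 6 libraries was left out (DAXX siRNA with crotonate 1: 35, and 2: 34; non-targeting with crotonate 1 to 4: 35, 37, 32 and 25). Lower calls fell to 72, 70, 65 and 70 without non-targeting crotonate libraries 1 to 4. Between the 2 knockdown comparisons, 13 higher genes were shared (0.0701 by chance) and 49 lower genes (0.367 by chance), and 200 of 201 genes called in either had the same sign.

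The lists that passed camera for DAXX siRNA in crotonate shifted downwards. Cholesterol synthesis genes had 0 of 25 called in the full table (1 higher and 4 lower over the list alone; camera adjusted p = 0.00453, estimated 0.326), and stem cell and Wnt target genes 0 higher and 1 lower of 20, the transcription factor gene SOX9 (1 and 4; adjusted p = 0.0299, estimated 0.387). Metallothionein genes gave 0 of 4 (0 and 3; adjusted p = 0.011, estimated 0.362), unfolded protein response genes 0 of 20 (adjusted p = 0.0226, estimated 0.362) and ribosomal protein genes 0 of 81 (adjusted p = 0.011, estimated 0.809).

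With non-targeting siRNA, crotonate raised NGFR and other genes. NGFR, the low-affinity neurotrophin receptor gene (chromosome 17, 49495293 to 49515008, plus strand), rose from 12.6 ± 1.54 to 47.4 ± 3.54 RPM (log2 fold change 1.91, SE 0.135, n = 4, adjusted p = 3.82e-08). VGF, a neuropeptide precursor gene, rose from 46.8 ± 9.36 to 122 ± 19.7 RPM and the fibronectin gene FN1 from 12.5 ± 0.303 to 31.1 ± 1.16 RPM (1.31). The neuronal calcium sensor gene HPCAL4 (1.41), the teneurin gene TENM3 (1.365), the axon guidance gene NTN1 (1.21), the sestrin gene SESN3 (1.35) and SH3BGRL2 (1.52) rose by similar amounts.

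The named genes that fell under crotonate changed less. CAV1, the main coat protein of caveolae, fell from 410 ± 35.1 to 231 ± 6.09 RPM (log2 fold change -0.82, SE 0.0734, n = 4, adjusted p = 3.19e-07), and the insulin receptor substrate gene IRS1 from 129 ± 14.3 to 73.3 ± 6.08 RPM. The adhesion receptor gene ADGRF1 (-0.90), the serotonin receptor gene HTR7 (-0.88), the keratin gene KRT80 (-0.84), the aldehyde dehydrogenase gene ALDH3B1 (-0.79), the histone acetyltransferase partner JADE2 (-0.73) and the epithelial transcription factor gene ELF3 (-0.71) also fell.

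Among genes of crotonylation, MLLT3, whose YEATS domain binds crotonyllysine, rose from 7.57 ± 0.541 to 16.7 ± 1.93 RPM (log2 fold change 1.14, n = 4, adjusted p = 3.77e-07). The acetyltransferase genes KAT2B and KAT2A went opposite ways (0.66 and -0.29), and the glutaryl-CoA dehydrogenase gene GCDH, whose enzyme makes crotonyl-CoA, fell by 0.39 log2 units (adjusted p = 0.0212). With 3 higher and 4 lower of 27 (3 and 4 over the list alone), the list of writers, erasers and readers did not pass camera ( adjusted p = 0.472, estimated 0.569). Genes of H3.3 chaperones and DAXX partners gave 0 higher and 2 lower of 29, among them the heterochromatin protein gene CBX5 (-0.41), picked after its value was seen (0 and 2; adjusted p = 0.109, estimated 0.384).

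Some genes known to respond to histone deacetylase inhibitors were higher with crotonate. DHRS2, a reductase gene, went from 4.3 ± 0.919 to 17 ± 1.14 RPM (log2 fold change 2.01, n = 4, adjusted p = 6.11e-08) and the heat shock gene HSPA2 from 4.76 ± 0.856 to 10.4 ± 0.776 RPM. Of 17 such genes 8 were higher and none lower (9 and 0 over the list alone; camera adjusted p = 0.000217, 0.187 with the correlation estimated from the data).

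Of intestinal stem cell and Wnt target genes, 13 of 20 were higher and none lower (13 and 0 over the list alone; adjusted p = 9.89e-05, estimated 0.123). The Wnt inhibitor genes NKD1 and DKK1 went from 12.2 ± 0.773 to 27.3 ± 2.29 and from 296 ± 23.2 to 499 ± 19.7 RPM (n = 4). Of 19 genes of the epithelial to mesenchymal transition, 11 were higher (12 and 0, camera adjusted p = 9.89e-05, estimated 0.0804), FN1 and the integrin gene ITGA5 (0.40) among them. Epithelial junction genes taken by the naming rule went both ways. The E-cadherin gene CDH1 (0.32) and CLDN1 (3.13, from 0.0674 to 0.476 RPM) rose, while KRT80 (-0.84) and CLDN7 (-0.38) fell. Of 31 immediate early and AP-1 genes, 11 were higher (13 and 1; adjusted p = 0.0121, estimated 0.569), with EGR1 up from 30.8 ± 2.59 to 64.3 ± 9.21 RPM and the phosphatase gene DUSP6 from 118 ± 7.64 to 176 ± 18.1 RPM.

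Targets of PPAR transcription factors included 6 of 14 higher (6 and 0 over the list alone; adjusted p = 0.0107, estimated 0.0804), with the acyl-CoA synthetase genes ACSL1 (0.47) and ACSL5 (0.41) named by the rule. Of 18 imprinted genes 7 were higher (8 and 1; adjusted p = 0.0107, estimated 0.192). Among them PEG10 rose from 39.5 ± 1.04 to 63 ± 2.95 RPM and the small GTPase gene DIRAS3 from 0.194 ± 0.0621 to 1.07 ± 0.234 RPM (n = 4).

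Of genes of the integrated stress response, 10 of 27 were lower with crotonate and none higher (0 and 13 over the list alone; adjusted p = 3.77e-10, estimated 0.0804). STC2, a secreted glycoprotein gene, fell from 82.7 ± 5.19 to 54.6 ± 3.07 RPM (log2 fold change -0.60, n = 4) and the glutathione-degrading gene CHAC1 from 11.7 ± 2.21 to 7.42 ± 0.382 RPM. DNA replication genes shifted downwards with 2 of 38 lower, MCM2 and MCM5 of the replicative helicase, picked after their values were seen (0 and 2; adjusted p = 0.000107, estimated 0.217). Ribosomal protein genes did so with 0 of 81 called (adjusted p = 2.28e-05, estimated 0.569), but their median of -0.063 became 0.00128 under quantile scaling, so they have no firm direction. No other list named here with a shift changed its direction under centring or quantile scaling.

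Other lists held called genes but did not pass camera, which compares a list with all other genes. Interferon-stimulated genes gave 13 higher and 1 lower of 38 (15 and 3 over the list alone; adjusted p = 0.0707, estimated 0.384), with HLA-B up from 96.3 ± 9.54 to 148 ± 4.14 RPM and IFI35 down from 5.57 ± 0.761 to 3.4 ± 0.325 RPM (n = 4). NF-kB and chemokine genes were split at 4 and 2 of 17 (5 and 2; adjusted p = 0.472, estimated 0.569): CXCL8 rose (0.92) and the NF-kB subunit gene NFKB1 fell (-0.30). NRF2 targets gave 5 and 1 of 24 (8 and 2; adjusted p = 0.799, estimated 0.868), and fatty acid oxidation genes 3 and 0 of 26 (3 and 0; adjusted p = 0.237, estimated 0.35). The positions of list genes in both crotonate comparisons are drawn in the chart of listed genes.

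**Figure D2:**
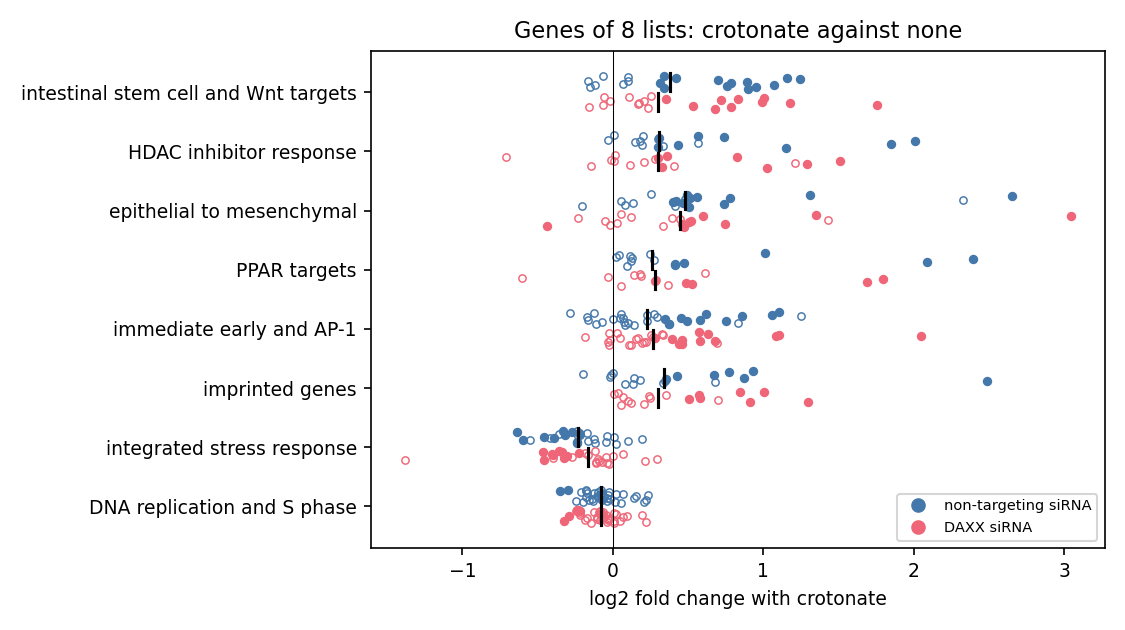
Log2 fold changes with crotonate of the genes of selected lists, with non-targeting siRNA and with DAXX siRNA. Each point is 1 gene, from n = 4 libraries per group.

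In all, 2352 genes were higher and 420 lower with crotonate and non-targeting siRNA, so 84.8% of called genes were higher. Limma-voom on recovered reads called 1782 higher and 902 lower. The split depends on the scaling: after centring each library on its median gene, which evens the sides by construction, the counts were 1458 and 1701 (46.2% higher), and after quantile scaling 1424 and 1010. Centring moved the median fold change of all genes by -0.129, from 0.074 to -0.055, so a small change in either direction is relative to that shift. Among genes changed by at least 1 log2 unit, 515 were higher and 12 lower. Lower calls fell to 267 without non-targeting library 1 and to 247, 278, 269 and 259 without crotonate libraries 1 to 4.

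Crotonate in DAXX siRNA cells moved many of the same genes. NGFR rose from 11.7 ± 2.8 to 41.6 ± 5.56 RPM (log2 fold change 1.85, n = 4, adjusted p = 3.4e-08), FN1 from 12.6 ± 1.2 to 32 ± 2.56 RPM and VGF from 58.7 ± 15 to 149 ± 42.4 RPM. HPCAL4 (1.34), MDGA1 (1.35), the actin-associated gene PDLIM3 (1.305), the pyrophosphatase gene ENPP1 (1.24) and the sulfatase gene SULF2 (1.21) also rose. CAV1 fell from 443 ± 27.5 to 251 ± 18.1 RPM, followed by ALDH3B1 (-0.82), the homeobox gene MKX (-0.72), ADGRF1 (-0.71), ELF3 (-0.65), IRS1 (-0.63), the retinal reductase gene DHRS3 (-0.63) and GTF3C6 (-0.62).

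Of DAXX partners, CBX5 fell from 179 ± 6.87 to 133 ± 11.4 RPM (log2 fold change -0.43, n = 4, adjusted p = 0.00328) and the kinase gene HIPK2 rose from 163 ± 11.7 to 220 ± 31.4 RPM (0.43). That list had 1 higher and 3 lower of 29 (1 and 3 over the list alone; adjusted p = 0.034, estimated 0.238). MLLT3 rose from 7.36 ± 0.195 to 14 ± 1.47 RPM and the deacylase gene SIRT2 by 0.47 log2 units. DHRS2 rose from 3.67 ± 0.688 to 10.4 ± 1.27 RPM, in a list of deacetylase inhibitor responses with 7 of 17 higher (8 and 0; adjusted p = 0.00938, estimated 0.238).

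The lists that passed camera upwards with crotonate in DAXX siRNA cells were those that did so with non-targeting siRNA. Stem cell and Wnt targets had 10 of 20 higher (11 and 0 over the list alone; adjusted p = 4.58e-05, estimated 0.116), with the ephrin receptor gene EPHB2 up from 28.9 ± 1.64 to 57.4 ± 3.98 RPM (n = 4). Immediate early and AP-1 genes had 12 of 31 (14 and 0; adjusted p = 0.000253, estimated 0.362), imprinted genes 7 of 18 (7 and 0; adjusted p = 0.00234, estimated 0.116) and PPAR targets 5 of 14 (9 and 0; adjusted p = 0.00938, estimated 0.116). Genes of the epithelial to mesenchymal transition had 8 higher and 1 lower of 19, the calcium-binding protein gene S100A4 (8 and 1; adjusted p = 0.0144, estimated 0.238).

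Of integrated stress response genes, 9 of 27 were lower again (0 and 11 over the list alone; adjusted p = 1.83e-07, estimated 0.116), STC2 (-0.46) and the serine synthesis gene PSPH (-0.40) among them. Ribosomal protein genes shifted downwards with 4 of 81 lower (0 and 0; adjusted p = 1.41e-17, estimated 0.238), RPL14 (-0.30), RPL27A (-0.27) and, outside the naming rule, RPS12 and RPS4X. DNA replication genes had 5 of 38 lower, UHRF1 and RFC4 and, outside the rule, PCNA, MCM2 and MCM4 (0 and 5; adjusted p = 0.000101, estimated 0.238), genes of G2 and mitosis 0 of 36 (adjusted p = 0.00164, estimated 0.393) and replication-dependent histone genes 2 lower of 26, HIST1H2AC and HIST1H4I, picked after their values were seen (0 and 0; adjusted p = 0.00938, estimated 0.238).

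In all, 2338 genes were higher and 433 lower with crotonate in DAXX siRNA cells (84.4% higher; limma-voom 1684 and 859). Centring gave 1515 and 1488 (50.4% higher) and moved the median of all genes by -0.116. At least 1 log2 unit of change was seen for 486 higher and 22 lower genes. Lower calls fell to 251 and 220 without DAXX siRNA libraries 1 or 3, and to 271 without crotonate library 2. Both crotonate comparisons shared 1655 higher genes (306 by chance) and 188 lower genes (10.1 by chance), and 3646 of 3700 genes called in either (98.5%) had the same sign. The fold changes of both treatments are set against each other in the scatter of effects.

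**Figure D3:**
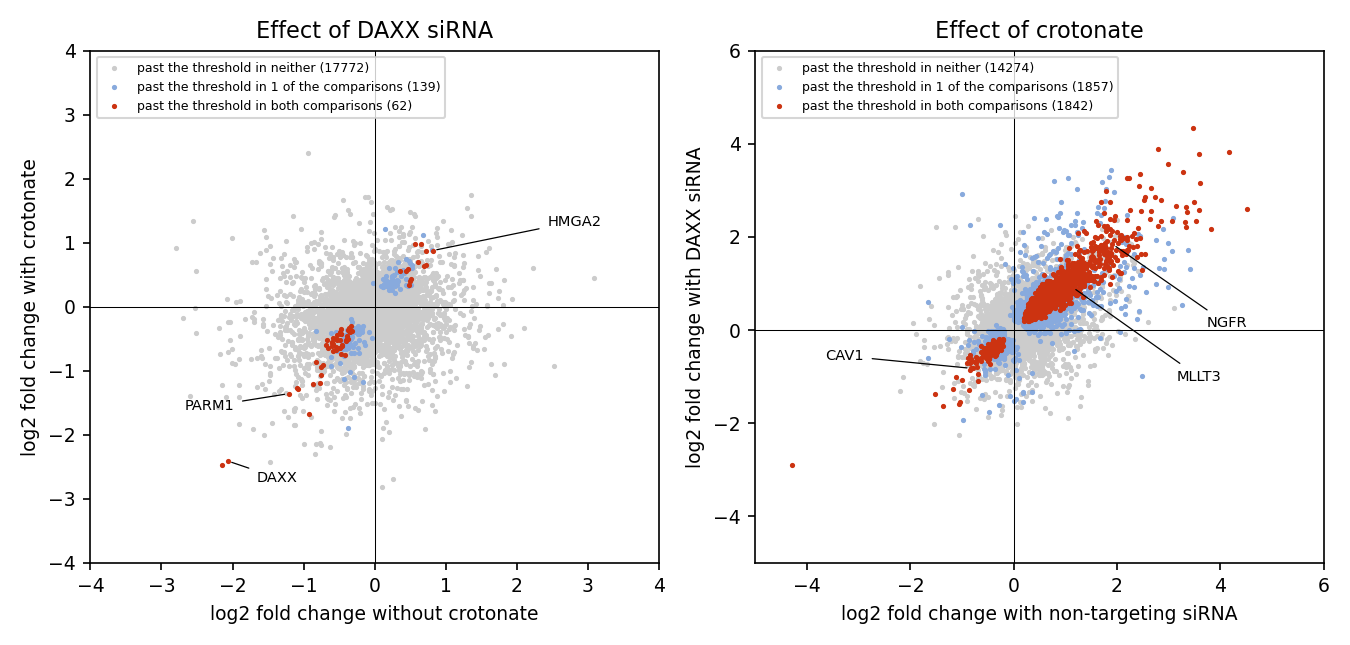
Log2 fold changes of RNA in 2 conditions: DAXX siRNA without and with crotonate, and crotonate with non-targeting and with DAXX siRNA. Each point is 1 tested gene, from n = 4 libraries per group.

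No gene passed for an interaction of DAXX siRNA with crotonate. DAXX itself had an interaction of -0.34 log2 units (SE 0.177, n = 4 per group, adjusted p = 0.995), HMGA2 rose by 0.82 without and 0.88 with crotonate, and PARM1 fell by 1.21 and 1.36. SPARC, picked after its value was seen, fell by 0.92 and by 1.67 log2 units, with adjusted p = 0.995 for the difference. Limma called 0 genes, with 433 (2.41%) at unadjusted p under 0.05 and a smallest adjusted p of 0.995, and limma-voom called 0. As lists, genes of G2 and mitosis (camera adjusted p = 0.0174, estimated 0.599) and ribosomal protein genes (3.68e-08, estimated 0.599) shifted downwards with 0 genes called.

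Anti-Kcr reads covered 49916 regions of 300 to 107400 bp (median 1800 bp, 157 Mb in total). Of these, 13743 (27.5%) lay within 2 kb of a gene start, 25360 (50.8%) elsewhere in a gene and 10813 (21.7%) outside genes. Signal exceeded input in 98.4% of regions with non-targeting siRNA, and by at least 2-fold in 49.1% (98.5% and 49.3% with DAXX siRNA). With crotonate these shares were 96.8% and 32.5% with non-targeting siRNA, and 97.4% and 36.8% with DAXX siRNA. The regions were called with MACS, per the processing notes, so signal above input is close to what selects a region. Which libraries they were called in is not given in the sources used here. An effect of that choice on the difference with crotonate was not tested. The median log2 ratio to input went from 0.986 ± 0.111 to 0.793 ± 0.0926 with non-targeting siRNA and from 0.998 ± 0.0854 to 0.84 ± 0.123 with DAXX siRNA (n = 3 without and 2 with crotonate).

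Fewer scaled anti-Kcr reads fell in the regions with crotonate. In units of M (10 to the power of 6 reads), it went from 3.52 ± 0.331 M (n = 3) to 3 ± 0.23 M (n = 2) with non-targeting siRNA, and from 3.54 ± 0.26 to 3.13 ± 0.322 M with DAXX siRNA, against 1.82 M for input. Libraries were scaled to a common size, so this is a share of reads and not a total amount of crotonyllysine. Regions near gene starts fell most, by a median of -0.331 with non-targeting and -0.246 with DAXX siRNA, against -0.186 and -0.134 elsewhere in genes and -0.157 and -0.113 outside genes. With 1A and 1B merged, crotonate changed the total by -0.203 log2 units, a fall of 13.2% (exact permutation p = 0.05 within siRNA, smallest possible 0.02). With every library on its own the change was -0.228 (exact p = 0.0222), and with libraries 2 and 3 only it was -0.154 (exact p = 0.167, smallest possible 0.0556). Reads of each library are drawn in the chart of anti-Kcr reads.

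**Figure D4:**
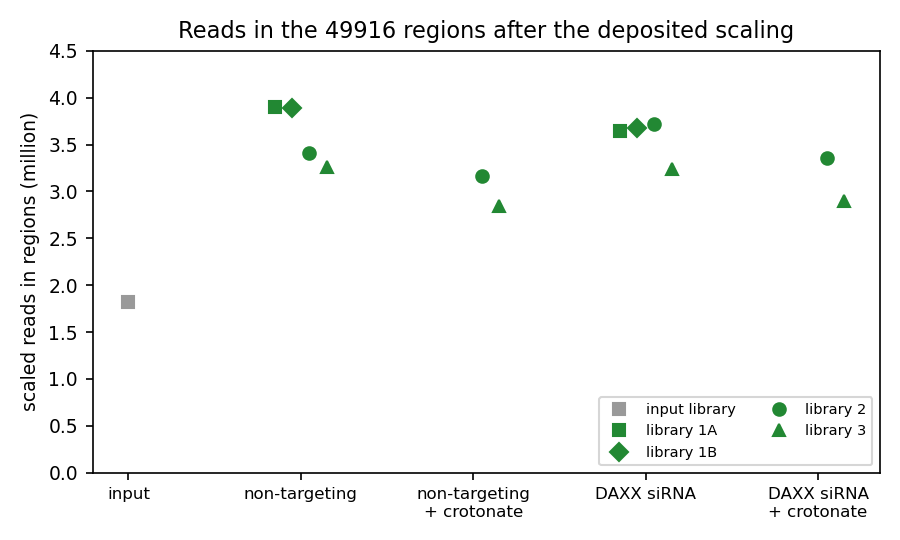
Scaled anti-Kcr reads in the 49916 regions for each library, in M (10 to the power of 6), by siRNA and crotonate, with the input. 1A and 1B count as 1 sample, giving n = 3 without and 2 with crotonate.

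The regions of largest fall that passed the test for crotonate with non-targeting siRNA held few reads. One lay in WBP4, a splicing factor gene (chromosome 13, 41063851 to 41064300), from 11.9 ± 2.39 to 2.59 ± 2.05 scaled reads (means of n = 3 and 2; log2 fold change -2.53, SE 0.533 and limma adjusted p = 0.0379 from the planned fit of 4 and 2 libraries, as for all regions below). Next came regions in THADA (chromosome 2, 43290751 to 43291350, -2.47), in the kinase gene FRK (chromosome 6, 116011951 to 116012700, -2.30), at the start of the centrosome gene OFD1 (chromosome X, 13734751 to 13735350, -2.26) and in the adhesion receptor gene ADGRV1 (chromosome 5, 90596551 to 90597150, -2.19). No single library had more than 20 reads in any of them. With DAXX siRNA the called regions lay in PHF10, a chromatin remodelling subunit gene (within 2 kb of the start of AL354892.1, chromosome 6, 169723051 to 169723950, -1.91, adjusted p = 0.0238), in ABR (chromosome 17, 1207951 to 1208850, -2.10) and outside genes (chromosome 10, 52447951 to 52448400, -2.71).

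With non-targeting siRNA, 0 regions were higher and 97 lower with crotonate, 60 of the 97 within 2 kb of a gene start, and with DAXX siRNA 0 and 3. The medians of all regions were -0.227 and -0.167, and centring moved them by 0.198 and 0.145. Merging 1A with 1B left 0 calls in both, and all 8 named regions were lost in at least 1 of 15 other settings, including centring, which left 4 and 0 lower. Leaving out 1 library moved the 97 lower calls to 1, 2 and 1 (non-targeting 1A, 1B or 2), 1880 with 5 higher (non-targeting 3), and 519 and 17 (crotonate 2 or 3). With DAXX siRNA lower calls were 0 without library 1A, 1B or 2 or crotonate library 3, and 1041 without crotonate library 2. So single regions lost with crotonate cannot be named with confidence.

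DAXX siRNA changed no anti-Kcr region past the test. Without crotonate, regions with small p lay in ATXN7L1, a SAGA complex gene relative (chromosome 7, 105794701 to 105795750), at 13.8 ± 2.91 and 27.5 ± 4.19 scaled reads (log2 fold change 1.16, n = 3 each), in C2CD2 (1.04), outside genes on chromosome 13 (73326001 to 73327350, 1.19), and at CXorf40B (-1.26) and in ACSL1 (-1.05). All had an adjusted p of 1. Limma called 0 of 49916 regions, with 1504 (3.01%) at unadjusted p under 0.05, and limma-voom called 0. With crotonate the smallest p belonged to a region outside genes on chromosome 14 (103258201 to 103258650, -2.78, adjusted p = 0.647), with ACYP2 (2.48) and PHF8 (-2.05) next (adjusted p = 0.999). Limma called 0, with 1909 (3.82%) at unadjusted p under 0.05, and limma-voom 0.

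For the interaction in anti-Kcr signal, a region in the histone demethylase gene PHF8 (chromosome X, 54043801 to 54044400) went from 10.3 ± 0.879 to 17.4 ± 2.1 scaled reads with crotonate and non-targeting siRNA, and from 16.1 ± 4.65 to 4.67 ± 2.92 with DAXX siRNA (interaction -2.69, n = 3 without and 2 with crotonate, adjusted p = 1). Regions in ACYP2 (2.81) and at ANKRD19P (2.08) went the other way. Limma called 0 regions, with 1697 (3.4%) at unadjusted p under 0.05, and limma-voom 0.

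Anti-Kcr signal at a gene correlated weakly with its RNA level, and not in every group once input was removed. Over 10580 genes with a region (58.9% of tested genes) the Spearman correlation was 0.104 with non-targeting siRNA and 0.106 with DAXX siRNA, and 0.0708 and 0.0853 with crotonate. Signal over input gave 0.0759 and 0.121 without crotonate, and -0.0155 and 0.0285 with it (non-targeting, then DAXX siRNA). Input alone gave 0.0773 and 0.0683, and 0.0646 and 0.0671 with crotonate. With non-targeting siRNA without crotonate, median signal over input was 1.02 and 1.09 in the genes of lowest and highest RNA level (median 0.802 and 138 RPM).

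Genes whose RNA rose with crotonate lost less anti-Kcr signal than other genes of like RNA level and like anti-Kcr reads per region. Those reads were not divided by input or region length. Signal over input, gene span and the place of regions were not matched. With non-targeting siRNA the fall grew with signal over input, from -0.161 in the weakest 20% of regions to -0.276 in the strongest. The comparison cannot tell less loss apart from a difference in enrichment. Percentiles measure spread over genes and not over libraries. With non-targeting siRNA the 1632 higher genes with a region had a median change of -0.23, against -0.266 for random sets (central 95% range -0.279 to -0.254, percentile 100 of 10000 sets). With DAXX siRNA the 1696 higher genes had -0.15 against -0.204 (-0.213 to -0.195, percentile 100). The 288 lower genes with non-targeting siRNA lay within the random range (-0.313 against -0.302, percentile 19.71), and the 264 lower genes with DAXX siRNA lost more than most sets (-0.267 against -0.223, percentile 0.03), at percentile 44.95 without crotonate library 3. Counting only regions at gene starts, higher genes stayed at percentile 100 in both, and lower genes were at 0.03 and 0. Genes changed by DAXX siRNA kept within the random range (percentiles 51.65 and 60.78 without crotonate, 48.8 and 24.16 with it). The comparison with random sets is drawn in the chart of anti-Kcr change at changed genes.

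**Figure D5:**
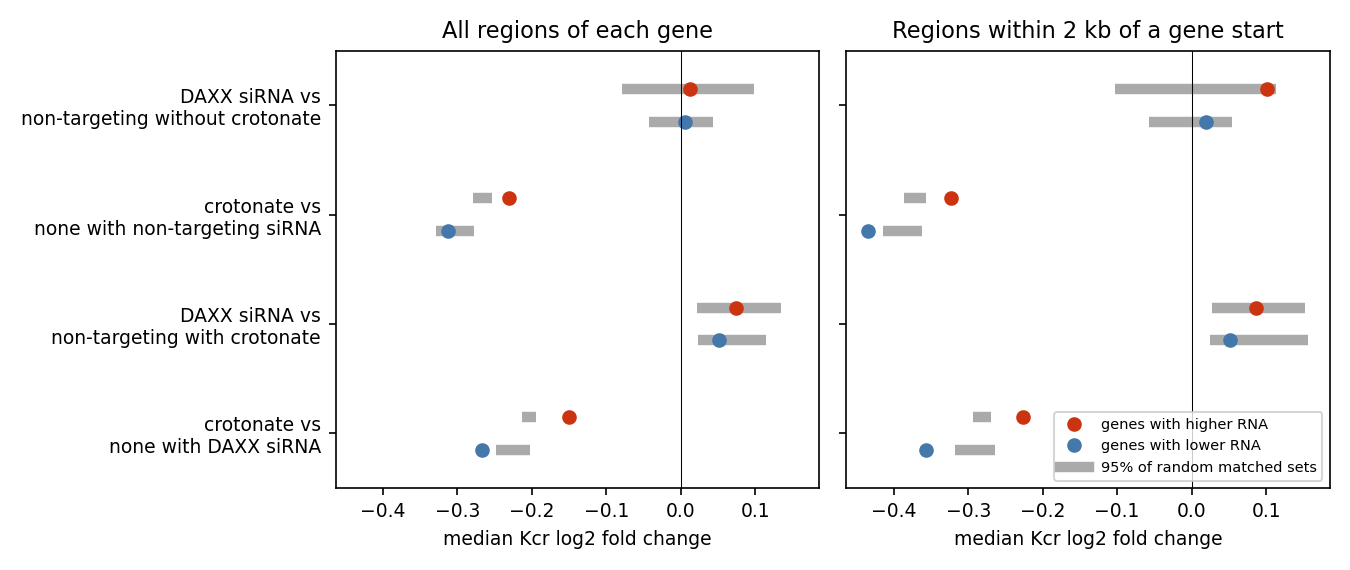
Median log2 change of anti-Kcr signal at genes whose RNA was higher or lower, against 10000 random gene sets. The sets were matched on RNA level and on anti-Kcr reads per region, not divided by input. ChIP changes come from the planned fit, which keeps 1A and 1B apart (4 libraries per siRNA without and 2 with crotonate).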

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

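In groups of 4 RNA libraries, 30 values of named genes lay far from the other 3 libraries of their group, of 339 gene and group pairs examined. Chance flags about 1 in 20, or 17 of them. They fall on 14 libraries, at most 4 in any 1.

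With non-targeting siRNA without crotonate, library 2 had high GAS6 (97.2 RPM, others 69.5 to 73.7), KAT2A (72.8, others 59.8 to 60.4), HLA-B (110, others 89.9 to 92.6) and the claudin gene CLDN7 (107, others 99.1 to 100). Library 1 had low PARM1 (16.8, others 19.6 to 19.9) and library 4 low STC2 (74.9, others 84.4 to 85.8). With crotonate, library 1 had low PEG10 (58.6, others 64.1 to 65) and CLDN1 (0.336, others 0.518 to 0.529), and high CYBRD1 (27.6, others 25.3 to 25.6). Library 2 had low ribonucleotide reductase subunit RRM2B (104, others 113 to 114) and DKK1 (470, others 506 to 512), and high hexokinase HK1 (166, others 144 to 146) and glucose phosphate isomerase GPI (650, others 550 to 559). Library 3 had low thiolase ACAA2 (22.2, others 24.4 to 24.8) and high CYP1A1 (8.02, others 7.16 to 7.27). Library 4 had low DAXX (95.2, others 102) and UHRF1 (196, others 225 to 228).

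With DAXX siRNA without crotonate, library 4 had high GAS6 (148 RPM, others 119 to 124) and low ACSL5 (33.2, others 34.7 to 35.1). Library 1 had high ENPP1 (8.15, others 6.9 to 7.11) and library 2 high STC2 (95.9, others 81.9 to 84.1). Library 3 had high CSF1, a cytokine gene (5.62, others 5.11 to 5.15), and ZNF22 (29.4, others 24.7 to 24.8), and low sulfiredoxin SRXN1 (151, others 161 to 162). With crotonate, library 1 had high CPA4 (60.2, others 44.9 to 47.3) and HPCAL4 (26.6, others 22.6 to 22.9) and low S100A4 (104, others 144 to 150). Library 3 had low IGSF3 (39.5, others 46.9 to 48.2), and library 4 high GAS6-AS1 (30.5, others 25 to 25.7) and ITGA5 (134, others 117 to 120).

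The 4 counts of called genes stood apart from other groupings. DAXX siRNA without crotonate gave 73 genes and with crotonate 190, and crotonate gave 2772 with non-targeting and 2771 with DAXX siRNA. Of 35 splits of the 8 libraries in each comparison, only 1, the real one, gave as many, and the highest other count was 0. For the interaction the real count of 0 was reached by 100 of 100 splits (highest other 68), and for anti-Kcr regions with DAXX siRNA without crotonate by 35 of 35 (highest other 0). Every split reaches a count of 0, so these say nothing on chance.

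Of the tests of patterns, the 2 on scaling were chosen after the results they bear on were seen, and the others were written before. The excess of higher genes under crotonate could come from scaling to RPM. Centring took the share of called genes that were higher from 84.8 to 46.2% (2772 and 3159 calls), but centring evens the sides by construction, so the cause of the excess among small changes stays open. Among genes changed by at least 1 log2 unit the share went from 97.7 to only 93.8% (527 and 404 genes), to 97.5% when every library was thinned to the shallowest (526 genes; 256 genes of any size gained or lost a call), and to 95.6% in the 20% of genes with the shortest span (68 genes). Centring moved the median of all genes by only -0.129, which could hardly turn a change of 1 log2 unit. The 93.8% was thus nearly set in advance and does not decide on scaling. It shows only that a shift of that size is too small to make changes that large. For genes with large changes the other values argue against depth and gene length as the whole cause. A broad activation of genes may remain, which was not tested.

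The fall of anti-Kcr reads in regions under crotonate may reflect the libraries numbered 1, which exist only without crotonate. Within libraries 2 and 3 the change was -0.154 log2 units (exact permutation p = 0.167, smallest possible 0.0556). In all libraries it was -0.203 with 1A and 1B as 1 sample and -0.228 with them apart. Each of the 4 pairs of the same number and siRNA fell (non-targeting 3.408 to 3.166 and 3.263 to 2.841 M reads, DAXX siRNA 3.723 to 3.357 and 3.243 to 2.902). Pairing by number was not settled, however. ChIP correlations leaned towards it (median 0.0431 within numbers, -0.00939 between) but were not tested. Without pairing, DAXX siRNA library 3 (3.243 M) lay below DAXX siRNA library 2 with crotonate (3.357 M), while the non-targeting libraries still separated. These libraries are too few to decide whether the libraries numbered 1 were the whole cause. A lower enrichment of the antibody libraries would hit the strongest regions most. The strongest 20% of regions fell by 0.0984 log2 units more than the weakest 20% (value -0.0984). Medians were -0.276 against -0.161 with non-targeting siRNA and -0.197 against -0.115 with DAXX siRNA. The strongest regions fell more in 8 of 8 library pairs with non-targeting siRNA, but in only 5 of 8 with DAXX siRNA. These pairs reuse the same libraries and keep the near-duplicates 1A and 1B apart, so they are not independent. A larger fall in the strongest regions is also what a real loss at marked sites would give. A competition of antibody with more crotonyllysine elsewhere in the genome was not tested.

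The effects of DAXX siRNA were somewhat larger with crotonate than without. Picking genes for a large effect in 1 condition could mimic this. For 682 genes picked by the mean of both effects, 433 (63.5%) were larger with crotonate. Limma's rotation test (fry) of the interaction, which rests on normal errors, gave an unadjusted p of 0.0378 for this 1 set. Leaving out 1 library moved it from 0.00243 to 0.845, so this is undecided. Less DAXX transcript was left with crotonate on average, but that call was lost in 9 of 16 other settings. DAXX also did not pass for the interaction. The ratio of the log2 falls of DAXX (1.17) lay within the interval of the slope of the other genes (1.15, 1.01 to 1.3). A stronger knockdown could thus be the cause as well as a biological interplay.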

How the results depend on the processing

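Most alternatives changed 1 choice at a time. Merging with centring changed 2. Limma-voom changed both the scaling, with size factors of its own, and the variance model. A shift under limma-voom therefore cannot be put down to either. Limma-voom, merging with centring, leave-one-out values for anti-Kcr change at RNA-changed genes, and gene families were chosen after seeing the data. The planned count models, their size factors and the pseudocount were not run: they were planned for deposited counts, and the deposited unit is log2. The reads recovered from it went into limma-voom only. Of the values compared, mostly counts of calls, 363 stayed the same, 76 were weaker, 31 stronger, 3 moved and 0 reversed. A count was taken as the same when equal, 0 included, or close in size, whichever genes or regions it held. Counts cannot reverse, so the 0 reversed tells little. Of 170 calls of named genes, 127 held in all of the 15 or 16 settings run for them and 43 were lost in at least 1 (ZHX1 and ZMAT3 in 13, SEL1L in 12, ACLY and CYP1A1 in 11), none with a change of sign. Quantile scaling and centring each kept 151. Not counted among these settings, a change of at least 1 log2 unit kept 41. Where no cause is given below, the cause was not tested.

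Crotonate RNA counts (higher and lower; non-targeting, then DAXX siRNA) were 1424 and 1010, 1448 and 852 under quantile scaling, 1458 and 1701, 1515 and 1488 after centring, 515 and 12, 486 and 22 at 1 log2 unit or more, and 902 and 859 lower in limma-voom. DAXX siRNA without crotonate gave 7 and 22 with only the 2 groups, 0 and 5 at 1 log2 unit or more, and 10 higher without the trend; with crotonate it gave 2 and 14 at 1 log2 unit or more. Ranges without 1 library, higher and lower, were 10 to 22 and 29 to 60 for DAXX siRNA without crotonate, 25 to 70 and 65 to 116 with it, 1804 to 2456 and 247 to 441 for crotonate with non-targeting, and 1781 to 2255 and 220 to 597 with DAXX siRNA.

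Anti-Kcr regions with crotonate and non-targeting siRNA (higher and lower) were 1 and 1 under quantile scaling, 3 and 3 in limma-voom, 0 and 4 after centring, 0 and 572 for regions above the median signal, 0 and 446 with only the 2 groups, 0 and 2 as ratio to input, and 0 and 0 with libraries 2 and 3 only, with 1A and 1B merged, and merged and centred. With DAXX siRNA the 3 lower regions became 0 in all of these except quantile scaling. With DAXX siRNA in crotonate, the ratio to input gave 1 lower. Ranges without 1 library were 0 to 5 higher and 1 to 1880 lower with non-targeting, 0 to 1041 lower with DAXX siRNA, 0 to 5 and 0 to 7 for DAXX siRNA in crotonate, and 0 to 1 each way for the interaction; a group left with 1 library is assumed to vary like the others. The change in anti-Kcr reads ranged from -0.281 to -0.176. The called regions had a median of 51.2 reads per library and 2550 bp, all regions 28.1 and 1800 bp; whether depth or length limits the calls was not tested.

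For pairing by replicate number, a block gave 39 higher for DAXX siRNA without crotonate, 1 and 929 anti-Kcr regions for crotonate with non-targeting siRNA, and 17 genes higher and 1 lower in both treatments. RNA correlations within numbers were -0.251 to 0.188 (median 0.0651, with 7 of 16 libraries matching their own number best). Between numbers they were -0.187 to 0.309 (median -0.024). ChIP correlations were -0.0124 to 0.0893 within numbers (median 0.0431, 8 of 12) and -0.0893 to 0.0386 between them (median -0.00939). The ChIP values leaned towards pairing by number and the RNA values less clearly. The ranges overlapped and were not tested, so pairing stays unsettled.

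Gene lists past camera (higher and lower) were 3 and 0 for DAXX siRNA without crotonate, 0 and 5 with it, 6 and 3 for crotonate with non-targeting, 6 and 7 with DAXX siRNA, and 0 and 2 for the interaction. All became 0 with the correlation estimated. Rotation tests (fry) gave 1 and 1, 0 and 5, 16 and 2, 14 and 2, and 0 and 0. Genes higher in both treatments went from 7 to 4 after centring, and genes lower in both from 0 to 1 under quantile scaling and 7 after centring. The correlation of anti-Kcr level with RNA (0.104) was 0.0905 by Pearson, 0.0708 in crotonate with non-targeting and 0.0853 with DAXX siRNA. The percentile of anti-Kcr change at lower genes was 0.03 at gene starts with non-targeting and 3.81 at 1 log2 unit or more with DAXX siRNA. Percentile ranges without 1 library were 20.4 to 76.4 and 9.9 to 77.6 (higher and lower, DAXX siRNA without crotonate), 40.3 to 77.25 and 22.3 to 81.9 (with it), 100 to 100 and 5.9 to 51.2 (crotonate, non-targeting), and 100 to 100 and 0 to 44.95 (crotonate, DAXX siRNA).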

Other observations

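Gene families grouped by symbol, chosen after the data were seen, moved with crotonate. Of 141 families tested, 9 of 16 KLF transcription factor genes were higher and none lower with non-targeting siRNA (camera adjusted p = 8.96e-05, 0.126 with the correlation estimated), and 12 of 16 with DAXX siRNA (1.06e-05, estimated 0.157). Integrin alpha genes had 6 of 12 higher (0.000133, estimated 0.0978), against 8 with DAXX siRNA (3.33e-05, estimated 0.0761). Semaphorin genes had 7 of 18 higher (0.00194, estimated 0.317), against 10 with DAXX siRNA (3.33e-05, estimated 0.186). DDX RNA helicase genes had 1 higher and 9 lower of 36 (4.37e-05, estimated 0.126), keratin genes 3 lower of 16 (0.000243, estimated 0.126) and nucleoporin genes 3 lower of 22 (0.000119, estimated 0.225). With DAXX siRNA these had 2, 3 and 1 lower (1e-04, 0.00459 and 0.00858; estimated 0.186, 0.207 and 0.359). Centring kept these directions, with 7 higher KLF and 14 lower DDX genes. All 13 protocadherin alpha genes were higher with non-targeting siRNA (5.87e-07, estimated 0.407), but 0 of 13 were called with DAXX siRNA (0.0558, estimated 0.729), they share exons and count as few independent genes, and quantile scaling left 2.

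Under the deposited scaling, a larger share of genes with long spans was called higher with crotonate, and no larger share was called lower. No test compared these shares. With non-targeting siRNA 6.79% of genes in the shortest 20% by span (median 2.65 kb) were higher, then 9.1, 10.9 and 15.1%, and 23.5% in the longest (median 149 kb). With DAXX siRNA the shares were 6.29 and 23.5% at the ends. Lower genes made up 1.95, 3.23, 2.64, 2.42 and 1.45% from shortest to longest with non-targeting siRNA. By RNA level, 8.44% of genes under 1 RPM were higher, 22.2% of those at 4 to 16 RPM and 5.42% of those above 64 RPM, against 0.385, 1.73 and 4.66% lower.

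Knockdown and crotonate shared 7 higher genes (2.36 by chance) and 0 lower genes (1.29 by chance). Of the genes lower with knockdown 13 of 55 were higher with crotonate, and of those higher with knockdown 2 of 18 were lower. The counts by chance take no account of the shared control. The fold changes of both treatments correlated at 0.201. Simulated noise around a shared control, with no effect at all, gave 0.502. Real effects widen the fold changes and so lower a correlation, so 0.201 and 0.502 cannot be compared directly. The covariance was 0.0276, against 0.0356 in the simulation. With the controls split between the treatments the correlation was -0.0866 (-0.127 to -0.0179 over 6 splits).

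Of fibroblast markers 3 genes were measured and 1 was higher in each crotonate comparison (COL6A3 by 1.22 with non-targeting, COL1A1 by 0.66 with DAXX siRNA). Of 5 neuron and glia markers SYN1 was higher in both (1.69 and 2.74), and of 3 leukocyte markers none was called. The 13 mitochondrially encoded genes had 0 calls, with median changes of 0.0989 and 0.242.

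RNA libraries held 35 to 55.13 M reads in genes, with 4.707 to 5.604% in the top 10 genes. The first component of RNA (26.87% of variance) separated crotonate, the third (8.096%) separated the siRNAs, and the second (11.66%) set non-targeting library 2 apart (score -0.7009). ChIP libraries held 2.227 to 3.639 M reads in regions and the input 1.719 M.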
